A study of Drosophila melanogaster with 7 samples.

How the data were processed

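Chromatin immunoprecipitation sequencing had been done on 7 libraries of Drosophila melanogaster cells, 6 from S2 cells (H3K4me2, H3K9me2, H3K36me3, H4K16ac, HP1 and the linker histone H1) and 1 from Kc cells (HP1). Per the labels' protocols, the precipitated DNA was sonicated, ligated to SOLiD adaptors, amplified for 17 cycles, and selected at 140 to 200 bp on a gel before SOLiD sequencing. The growth protocol deposited with the Kc library names S2 cells, while its title and its cell line label name Kc. The group of every library was taken from its title. Each group holds 1 library, and no input or untreated control library was analysed here.

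Each deposited file lists aligned reads, 1 interval per line, with a chromosome, a start, an end, a read name, an unlabelled whole number in column 5 and a strand, and has no header. The intervals at the start of each file, where the length was checked, were all 49 bp long. Column 5 of the deposited files was treated as a score of unknown meaning. It ran from 0 to 3 in 6 libraries and from 0 to 5 in the HP1 library from S2, where 28.5% of the reads had a value above 3. The aligner is not given in the sources used here. Per the submitters' processing notes, SICER was among the tools for every library and dm3 was the genome build of the H1 and Kc libraries. The build of the other 5 libraries is not given in the sources used here, and their sequence names match those of the libraries on dm3. The gene table at hand belongs to another assembly, Release 6. No gene name or gene coordinate was therefore joined to the reads, and regions are given by position.

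From the deposited read intervals, reads were placed at their 5′ ends and counted, with 1 read kept per start position and strand. Between 5.06% (H1) and 19.5% (H3K36me3) of the reads were removed in this way. Counts were taken in 1-kb windows of the sequences 2L, 2R, 3L, 3R, X, 4, the Het sequences (assembled heterochromatin assigned to a chromosome) and U (unplaced sequence). A window was kept when at least 5 of the 7 libraries had 1 read or more. This rule left 121856 of 139664 windows, 95.5% of those of the 4 autosomal arms, 93.9% of those of X, 90.8% of those of chromosome 4, 54.8% of those of the Het sequences and 22.5% of those of U. Only 1 window of YHet was kept.

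Density was expressed over the library's own median on 2L, 2R, 3L and 3R. That median was 19 reads per kb for H3K4me2, 32 for H3K9me2, 17 for H3K36me3, 12 for H4K16ac, 38 for HP1 in S2, 45 for H1 and 18 for HP1 in Kc. At these depths the counting error of a single 1-kb window at the median ranged from 14.9% (H1) to 28.9% (H4K16ac). Medians of windows are whole reads, so ratios of medians move in steps. Log2 values were computed after adding a pseudocount of 1 read per window.

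The X to autosome ratio is the median density of X over that of the autosomal arms. Within S2, the ratio of each library was divided by that of H3K4me2, a reference chosen in advance, because libraries of 1 line share the number of DNA copies. Heterochromatin was described by the median density on chromosome 4, on the 1 Mb of each arm next to the centromere (proximal), and on the Het and U sequences. Spearman's rho was computed across 1-kb windows, which are not independent replicates. H4K16ac-rich windows had at least 2 times the H4K16ac median of their chromosome class, and H4K16ac-poor windows lay below that median. A window was called enriched at 2 or more times the autosomal median, and overlaps were divided by the number that independent lists would share. HP1 in S2 was compared with HP1 in Kc as a log2 ratio per window, each library scaled to its autosomal median. The counting noise behind 2-fold windows was drawn 20 times from Poisson counts, around the share of S2 in the pooled HP1 reads of each region.

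No p-value was computed, since each condition has 1 library. Errors are 95% intervals from 1000 resamples of 500-kb blocks. Blocks of 100 kb were used for chromosome 4, the proximal stretches and the Het and U sequences, which are too short for longer blocks. The overlaps, which include these regions, also used blocks of 100 kb, so their intervals rest on shorter blocks than those of the arms. For the values in 100-kb windows, blocks of 1 Mb were resampled. Shares of reads have Wilson intervals. These intervals cover variation along the genome and counting error in the given library, and reads without molecular identifiers are not independent molecules.

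The rule for named regions was written before the data were examined. It takes the 10 runs of adjacent 10-kb windows at 2 or more times the autosomal median with the most reads above that median in each library. For HP1 it takes the 10 highest and the 10 lowest 10-kb windows by S2 over Kc, with at least 50 reads in each library. The comparison of the lines was tested on simulated counts, with 400 of 92262 autosomal windows raised in S2. Of those raised 2-fold 51% were recovered, and of those raised 4-fold 100%. A 2-fold change lies on the threshold itself, so a recovery near 51% follows from the design. Changed windows were drawn only where Kc had enough simulated reads, and recovery of windows higher in Kc was not tested. Of the unchanged windows, 1.69% were called higher in S2 and 1.23% higher in Kc.

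Alternatives set in advance were all reads as deposited, 5-kb windows, other window filters, means in place of medians, other reference libraries, 500 kb next to the centromere, other thresholds, a pseudocount of 5 reads, thinning to the shallowest library, a shift of 75 bp, total-read scaling and local centring. Profiles around genes, the gene lists and the GC correction needed a genome or annotation of the build of the files and were not run. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.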

Results

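Binding of heterochromatin protein HP1 was mapped in S2 cells, a Drosophila line of male origin, and in Kc cells, a line of female origin. In S2 cells the linker histone H1 and 4 histone marks were mapped as well. H3K4me2 marks promoters and enhancers, H3K36me3 marks the bodies of transcribed genes, H3K9me2 is a mark of heterochromatin, and H4K16ac is the acetylation that the dosage compensation complex places on the X chromosome of males. Each of the 7 libraries is the only one of its group, so no difference between conditions could be tested against the spread between cultures.

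The libraries held 7733442 aligned reads for H3K4me2, 5280987 for H3K9me2, 9061463 for H3K36me3, 6868797 for H4K16ac, 5804817 for HP1 in S2, 5649456 for H1 and 2971033 for HP1 in Kc. The Kc library was the shallowest and had a median of 18 distinct reads per kb on the autosomal arms, against 38 in the HP1 library from S2. At these medians, counting alone gives 95% ranges of 10 to 27 reads for a 1-kb window in Kc and of 26 to 51 reads in S2. Values for whole chromosomes therefore rest on far more reads than values for single windows, and the first are the firmer.

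The series relates H4K16 acetylation to H1 and HP1 on the X chromosome of male cells. In S2 cells, H4K16ac was the only one of the 6 libraries with a higher density on X than on the autosomal arms. X held 36.5% of all H4K16ac reads (Wilson interval 36.5% to 36.6%), against 14.8% of the H3K4me2 reads, 10.1% of the HP1 reads and 9.50% of the H1 reads. The median density of H4K16ac on X was 1.42 times that of the autosomal arms (1.17 to 1.83), and the mean was 2.39 times. H1 had the lowest ratio, 0.467 (0.426 to 0.5). The ratio was 0.605 (0.538 to 0.649) for HP1, 0.588 (0.5 to 0.647) for H3K36me3, 0.656 (0.588 to 0.733) for H3K9me2 and 0.684 (0.579 to 0.789) for H3K4me2. In the Kc library, HP1 on X stood at 0.944 of the autosomal median (0.842 to 1.06). The intervals of HP1 on X in S2 and in Kc did not overlap. These ratios hold the number of X copies of each line, for which no input library was analysed here.

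**Figure D1:**
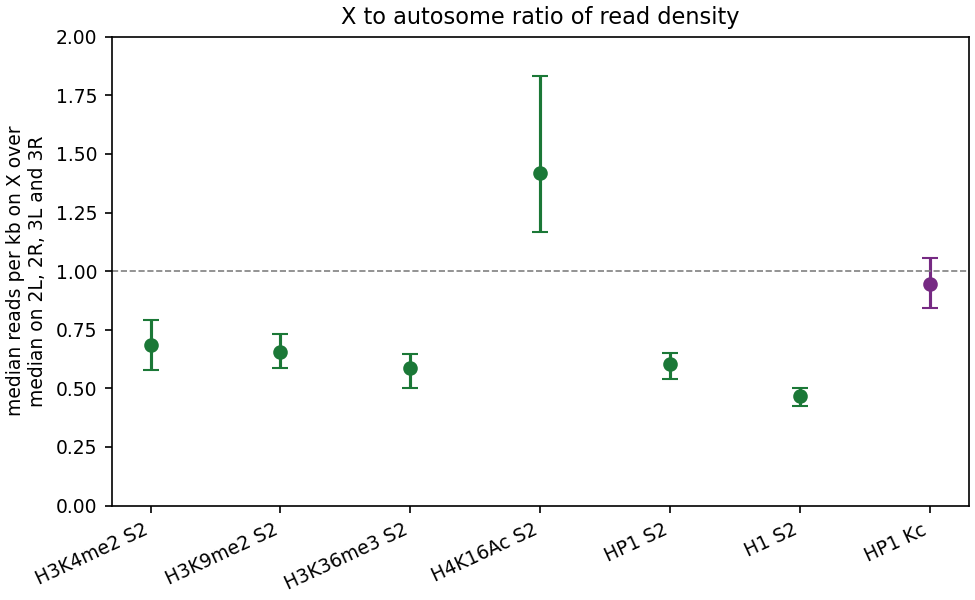
Median read density on X over the median on 2L, 2R, 3L and 3R (vertical axis, a ratio without unit) for each library, S2 in green and Kc in purple; bars are 95% intervals from resampled 500-kb blocks and the dashed line marks equal density. H4K16ac lies at 1.42, HP1 in Kc at 0.944, and the other 5 S2 libraries between 0.467 and 0.684.

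Within S2, X copy number is shared by all libraries and leaves the ratio of ratios. Relative to H3K4me2, H4K16ac on X was 2.07 times higher (1.83 to 2.45), while H1 was at 0.682 (0.584 to 0.792). H3K36me3 on X was at 0.860 of H3K4me2 (0.756 to 0.931). HP1 on X was at 0.885 (0.758 to 0.980) and H3K9me2 at 0.959 (0.823 to 1.13). The place of HP1 on X depended on the reference library, since HP1 stood at 1.03 when H3K36me3 was the reference.

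Runs of H4K16ac were ranked by their reads above the median, which favours long runs. Of the 10 runs with the most H4K16ac reads above the median, 9 lay on X. In the leading run, X from 1890001 to 2250000, H4K16ac reached 28.9 times the autosomal median, with H3K36me3 at 9.21, H3K4me2 at 8.22, HP1 at 1.31 and H1 at 0.735 times theirs. X from 15590001 to 15850000 had 25.4 times the autosomal median of H4K16ac, with HP1 at 1.12 and H1 at 0.579. X from 19490001 to 19660000 had 20.8 times, with HP1 at 0.771 and H1 at 0.364. X from 16160001 to 16360000 had 16.1 times, with HP1 at 0.598 and H1 at 0.297. The autosomal member of the list was 3L from 490001 to 730000, where H4K16ac was at 12.6 times the median, H3K4me2 at 11.1, HP1 at 3.37 and H1 at 2.18.

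On X and on the autosomal arms, the H4K16ac-rich windows as a class had a lower median H1 and a higher median HP1 than the H4K16ac-poor windows. H4K16ac-rich windows of X (8095 windows) had a median log2 H1 density that differed by -0.28 (-0.50 to -0.19) from that of H4K16ac-poor windows. On the autosomal arms the difference was -0.20 (-0.28 to -0.13). For HP1 the same difference was 0.66 on X (0.58 to 0.83) and 0.82 on the autosomal arms (0.73 to 0.87). H3K9me2 was higher in the H4K16ac-rich windows by 0.53 on X (0.29 to 0.67) and by 0.88 on the autosomal arms (0.79 to 0.97), and by 0.29 and 0.55 after centring on the surrounding 200 kb. HP1 of the Kc library, read over the same windows sorted by H4K16ac of S2, differed by 0.74 on X and by 0.85 on the autosomal arms. X minus autosomal arms gave -0.35 for H3K9me2 (-0.62 to -0.18), an interval that excludes 0. It gave -0.07 for H1 (-0.30 to 0.03) and -0.16 for HP1 (-0.24 to 0.06). Neither of these intervals excludes 0, so a difference between X and the autosomal arms was not detectable for H1 or HP1 with these libraries. In alternatives added after seeing the data, the autosomal difference of HP1 was 0.51 after centring on the surrounding 200 kb, and that of H1 was -0.32, with X at -0.45, in windows with at least 50% of the Kc HP1 median.

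H1 did not fall steadily with H4K16ac on X or on the autosomal arms, and was higher in the class with the most H4K16ac than in the class with the least. The windows of X were sorted by H4K16ac into 10 classes of nearly equal size. In the class of X with the least H4K16ac, H1 stood at 0.356 of the autosomal median, and in the fifth at 0.622. It was at 0.267 in the eighth class of X and at 0.556 in the class with the most H4K16ac. On the autosomal arms, H1 went from 0.667 in the lowest class to 1.40 in the sixth and 0.711 in the highest. HP1 on the autosomal arms was at 0.553 in the lowest class and 1.55 in the highest. HP1 on X went from 0.316 to 1.03. H3K9me2 on X did not rise steadily, with 0.344 in the lowest class, 0.8125 in the fifth, 0.5625 in the eighth and 1.125 in the highest. The lowest class was below the second in all 7 libraries on X and on the autosomal arms.

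**Figure D2:**
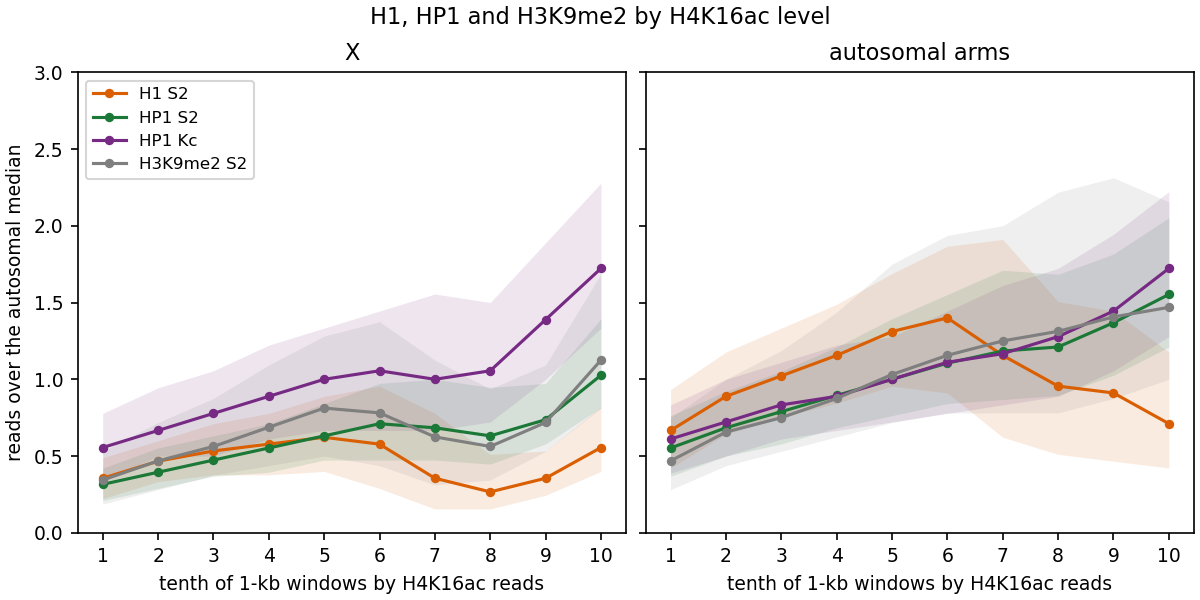
Median density of H1, HP1 and H3K9me2 over the autosomal median of each library (vertical axis, a ratio without unit) in 10 classes of 1-kb windows sorted by H4K16ac reads (horizontal axis), on X and on the autosomal arms; shading spans the 25th to 75th percentile of windows. On the autosomal arms H1 reaches 1.40 in the sixth class and 0.711 in the highest, while HP1 in S2 climbs from 0.553 to 1.55.

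Across 1-kb windows of S2, H4K16ac followed the marks of active genes on X and on the autosomal arms. Spearman's rho with H3K4me2 was 0.810 on X (0.792 to 0.825) and 0.839 on the autosomal arms (0.831 to 0.846). With H3K36me3 it was 0.759 on X and 0.722 on the autosomal arms. H4K16ac and HP1 correlated at 0.548 on X (0.496 to 0.595) and 0.541 on the autosomal arms (0.505 to 0.573). H4K16ac and H1 had a rho of 0.00895 on X (-0.0566 to 0.0667) and 0.0437 on the autosomal arms (0.0123 to 0.0728). The sign of the autosomal value was not stable, as Pearson's r was -0.0121 (-0.0468 to 0.0239) and rho was -0.0462 in windows with at least 50% of the Kc HP1 median. HP1 was closest to H3K9me2, with a rho of 0.726 on X (0.701 to 0.752) and 0.816 on the autosomal arms (0.803 to 0.827). H1 and H3K9me2 had a rho of 0.676 on X and 0.644 on the autosomal arms. HP1 and H1 had 0.473 on X and 0.490 on the autosomal arms. Random parts of the HP1 library from S2, each with 50% of its reads, correlated at 0.739 on X and 0.835 on the autosomal arms. S2 libraries share copy number and mappability, which adds to these correlations.

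HP1 and H3K9me2 are marks of heterochromatin, which in Drosophila fills the sequence around the centromeres and most of chromosome 4. HP1 in S2 on chromosome 4 was at 2.24 times the autosomal median (2 to 2.38), and HP1 in Kc was at 1.11 (0.944 to 1.33). On chromosome 4 of S2 cells, H3K9me2 was at 1.47 (1.23 to 1.71), H3K36me3 at 2 (1.59 to 2.65), H4K16ac at 2.42 (1.92 to 3.33), H3K4me2 at 1.05 (0.921 to 1.26) and H1 at 0.789 (0.674 to 0.932). Means over windows were lower on chromosome 4 for H4K16ac (1.22), H3K36me3 (1.26) and H3K4me2 (0.668). The means of HP1 there were 2.16 in S2 and 1.46 in Kc. HP1 was at least 2 times the autosomal median in 57.5% of the windows of chromosome 4 in S2 and in 27.0% of them in Kc.

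On the proximal 1 Mb of the 5 arms together, X included, HP1 was at 1.29 in S2 (1.08 to 1.54) and at 1.72 in Kc (1.47 to 1.89). On the Het sequences it was at 1.45 in S2 (1.31 to 1.57) and at 1.94 in Kc (1.68 to 2.06). In S2, H3K9me2 on the Het sequences stood at 0.875 (0.794 to 1) and H1 at 0.511 (0.457 to 0.556), and the 3 marks of active genes lay between 0.25 and 0.294, with means over windows between 0.157 and 0.227. Among the proximal stretches, 2L had the highest HP1 in S2, at 2.80 (2.44 to 3.21), with Kc at 2.28 (1.78 to 3), and 2R was at 2.61 in Kc (2.11 to 3) and 1.91 in S2 (1.67 to 2.18). Within 500 kb of the centromere, HP1 in Kc was at 3.11 on 2L and 2.33 on 2R. Proximal 3L was at 1.5 in S2 (1.32 to 1.65) and 1.39 in Kc (1.21 to 1.5), but at 0.811 and 0.667 with all windows kept, and proximal 3R was at 1.08 (0.95 to 1.23) and 1.67 (1.37 to 2). Proximal X had HP1 at 0.684 in S2 (0.564 to 0.737) and 1.22 in Kc (1 to 1.33), and at 0.486 and 0.778 with all windows kept. The enrichment of the Het sequences rests on windows with reads in 5 of the 7 libraries. With all windows kept, HP1 on the Het sequences was below the autosomal median and higher in S2 than in Kc, at 0.432 and 0.333, and HP1 on the proximal arms at 0.973 in S2 and 1.28 in Kc. On the Het sequences of S2, H3K9me2 was then at 0.167, H1 at 0.0909 and the marks of active genes between 0 and 0.0625.

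The runs with the most HP1 in S2 were led by a run near the proximal end of 2L and a run on 3R. In the leading run, 2L from 21700001 to 21980000, HP1 was at 4.47 times the autosomal median in S2 and 1.48 in Kc, with H3K9me2 at 4.42 and H1 at 2.23. In 3R from 18600001 to 18920000, HP1 was at 3.06 in S2 and 0.960 in Kc, with H3K9me2 at 4.84 and H1 at 2.66. In 2L from 21990001 to 22200000, HP1 was at 3.60 in S2 and 1.77 in Kc. In 3L from 510001 to 670000, HP1 was at 3.94 in S2 and 1.69 in Kc, and H3K4me2 was at 13.5 and H4K16ac at 14.3. The fifth run was on chromosome 4, from 370001 to 580000, with HP1 at 3.10 in S2 and 2.50 in Kc. In Kc the leading run was 3RHet from 590001 to 660000, with HP1 at 8.11 in Kc and 2.41 in S2. It was followed by 2L from 470001 to 580000 (3.92 in Kc, 2.53 in S2), 2R from 800001 to 920000 (3.52 and 2.87), 2R from 950001 to 1050000 (4.01 and 2.56) and 3L from 140001 to 220000 (4.74 and 1.27).

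Relative to the number of windows that independent lists would share, HP1-enriched windows of S2 overlapped more with H3K9me2 and H1 than with the marks of active genes. Of 14692 HP1-enriched windows in S2, 11030 were H3K9me2-enriched, 4.18 times the number of independent lists (3.97 to 4.41). The overlap with H1 was 4.43 times (4.18 to 4.70), with 4967 shared windows, and that with HP1 of Kc 3.54 times (3.34 to 3.77), with 7014 shared windows against 1980 from independent lists. The overlap was 1.95 times with H3K36me3 (7358 shared windows), 1.64 times with H3K4me2 (6436) and 1.54 times with H4K16ac (7521), whose longer lists share more windows with HP1 than the list of H1 does. A longer list also limits the fold that a mark can reach. The S2 libraries share copy number, which can add to their overlaps with HP1 of S2 and is not shared by the Kc library. The size of the overlap moved with the threshold, and the top 5% of windows gave 10.5 times for H3K9me2, 7.53 times for H1 and 8.37 times for HP1 of Kc. In these lists of equal length H3K36me3 was at 2.62, H3K4me2 at 1.95 and H4K16ac at 1.79. At 3 times the median H3K9me2, H1 and HP1 of Kc were at 8.56, 13.9 and 9.94, so the order of H3K9me2 and H1 depended on the threshold. X held 2.75% of the HP1-enriched windows of S2 and 13.5% of those of Kc, and 21045 of the 121856 kept windows. The threshold rests on the autosomal median, while the median HP1 of X was at 0.605 in S2 and 0.944 in Kc. These shares therefore also hold the difference in the level of X as a whole.

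**Figure D3:**
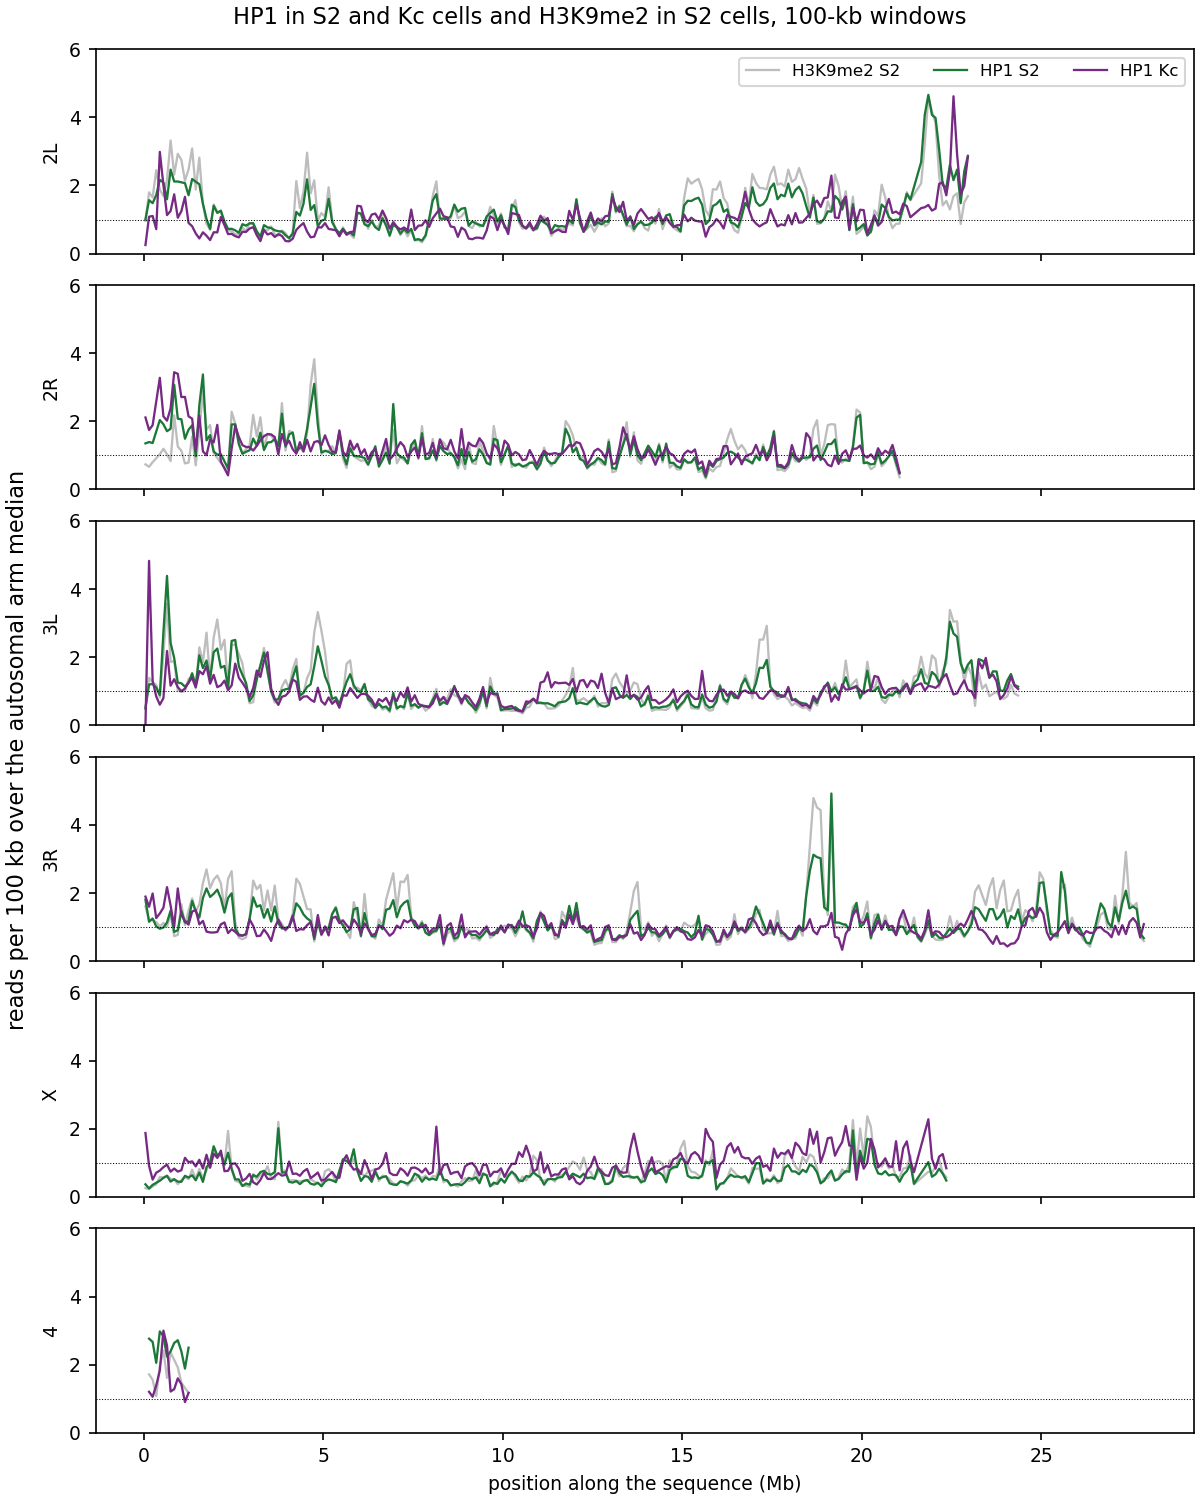
Reads per 100 kb over the autosomal arm median (vertical axis, a ratio without unit) along the 4 autosomal arms, X and chromosome 4 (horizontal axis, Mb) for HP1 in S2 (green), HP1 in Kc (purple) and H3K9me2 in S2 (grey); windows of 100 kb with fewer than 50 kept 1-kb windows are left out. HP1 in S2 follows H3K9me2 on the autosomal arms, and HP1 in Kc lies above HP1 in S2 along most of X, where the medians are 0.944 and 0.605.

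HP1 was compared directly between S2 and Kc after each library was scaled to its autosomal arms. HP1 on X was lower in S2, with a median log2 ratio of -0.73 (-0.84 to -0.61), and HP1 on chromosome 4 was higher in S2, at 0.89 (0.66 to 1.09). In the 54.8% of Het windows that passed the filter, HP1 was lower in S2, at -0.42 (-0.51 to -0.34), while the median densities with all Het windows had the other order (0.432 in S2 and 0.333 in Kc). In the filtered windows 3RHet was at -0.80 (-0.92 to -0.70), 3LHet at -0.37 (-0.50 to -0.26) and 2RHet at -0.20 (-0.29 to -0.09), while 2LHet, with 187 windows, was at 0.23 (0.02 to 0.55). XHet was at -1.03 (-1.19 to -0.96) and U at -0.55 (-0.62 to -0.47). Among the proximal stretches, X was at -0.84 (-1.12 to -0.66), 3R at -0.59 (-0.73 to -0.40) and 2R at -0.49 (-0.60 to -0.33). Proximal 2L was at 0.03 (-0.21 to 0.51), an interval that includes 0, and proximal 3L at 0.09 (0.06 to 0.14), a value that became -0.05 with a pseudocount of 5 reads. All autosomal arms together were at -0.08 (-0.13 to -0.02), at -0.22 with a pseudocount of 5 reads and at 0.05 when scaled to total reads, and single arms lay between -0.27 for 2R (-0.33 to -0.20; -0.15 when scaled to total reads) and 0.11 for 2L (-0.03 to 0.27), which was at -0.08 with a pseudocount of 5 reads. The lines also differed in depth, and only the S2 library kept reads with column 5 above 3. Without these reads the Het sequences were at -0.62, U at -0.92, 2RHet at -0.37 and 2LHet at 0.07. In 5-kb windows U was at -0.27, and scaled to total reads 2RHet was at -0.08. With a pseudocount of 5 reads 2LHet was at 0.10.

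**Figure D4:**
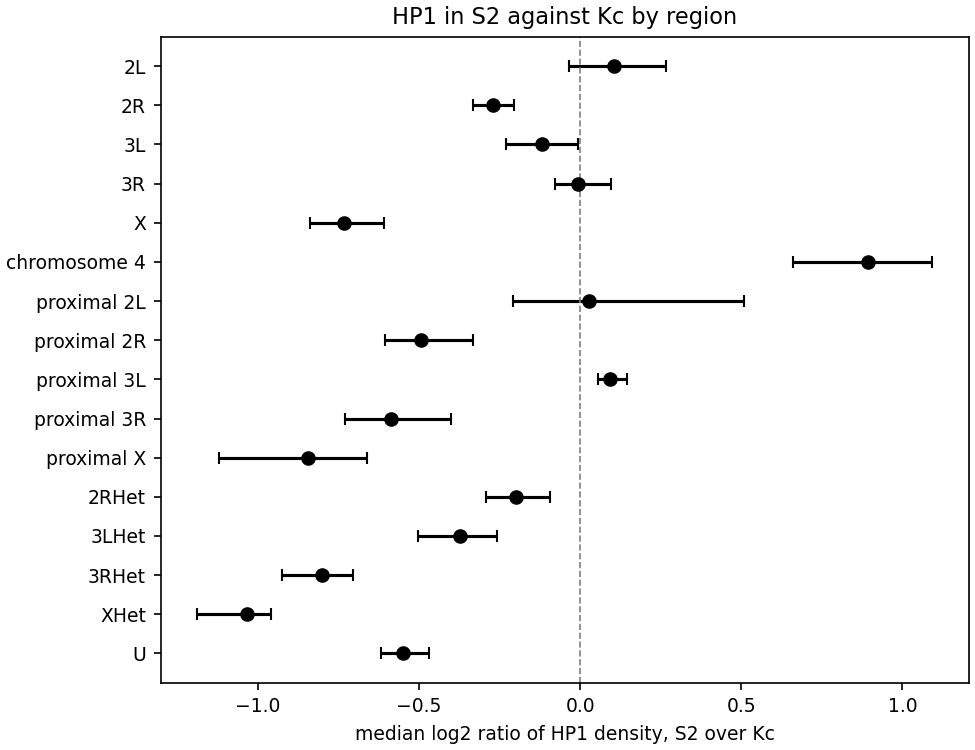
Median log2 ratio of HP1 density, S2 over Kc (horizontal axis), by region (vertical axis), after scaling each library to its autosomal median; bars are 95% intervals from resampled blocks of 500 kb (arms and X) or 100 kb (the other regions). Chromosome 4 lies at 0.89 and X at -0.73.

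Single windows differed in both directions. On the autosomal arms, 9.53% of windows were at least 2-fold higher in S2 and 6.83% at least 2-fold higher in Kc, where counting noise alone gave 1.67% and 1.24%. Centred on the surrounding 200 kb, the autosomal arms gave 4.27% and 2.39%. With a pseudocount of 5 reads they gave 4.66% and 7.11%, so which line had more such windows depended on the pseudocount. On X, 2.61% were 2-fold higher in S2 and 35.8% higher in Kc, where noise around the pooled read share of X gave 0.237% and 25.6%. Centred on the surrounding 200 kb, X gave 5.58% and 4.04%, a setting that by construction removes a difference in the level of X as a whole. The autosomal windows higher in S2 had a median H3K9me2 density of 2.06 and an H1 density of 1.33, while those higher in Kc were at 0.688 and 0.756. Chromosome 4 had 545 windows 2-fold higher in S2 and 26 higher in Kc among 1202, which is 45.3% and 2.16%. Noise around the share of S2 in the pooled HP1 reads of chromosome 4 gave 9.78% and 0.116%. Means of HP1 on chromosome 4 were at 2.16 in S2 and 1.46 in Kc, and medians at 2.24 and 1.11. This noise therefore lies around a smaller difference than the median log2 ratio, and noise around that ratio was not drawn.

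Of 12695 windows of 10 kb with enough reads in both libraries, the 10 with the highest S2 over Kc ratio included 5 on 2L between 1390001 and 1590000. The leading one, 2L from 1400001 to 1410000, had a log2 ratio of 2.62 (counting interval 2.30 to 2.95), with H1 at 2.36 and H3K9me2 at 2.30. X from 3760001 to 3770000 followed at 2.51 (2.25 to 2.77), with H4K16ac at 46.0, H3K4me2 at 21.9, H3K9me2 at 3.30 and H1 at 2.09. 2R from 6970001 to 6980000 was at 2.43 (2.25 to 2.61), with HP1 at 7.65 in S2 and H4K16ac at 53.7. There H3K9me2 was at 5.65 and H1 at 2.96, so in both windows the other S2 libraries were raised as well. The 10 windows highest in Kc included 3 on X, 3 on U and 2 on 2R. X from 20001 to 30000 had a log2 ratio of -5.38 (-5.75 to -5.01), but there the S2 libraries were nearly empty, with H1 at 0.125, H3K9me2 at 0.0954 and H3K4me2 at 0.152. H1 was also low in the 3 windows of U (0.0987 to 0.200), in 2R from 1150001 to 1160000 (0.0548) and in X from 21680001 to 21690000 (0.305). A high ratio for Kc in such windows may reflect few S2 reads of any kind. H1 was at 1.40 in 3R from 930001 to 940000 and at 1.41 in 3L from 150001 to 160000. The log2 ratio was -4.61 (-4.82 to -4.39) in X from 8110001 to 8120000, where H1 was at 0.636, and -4.26 (-4.50 to -4.01) in 2R from 21120001 to 21130000, where H1 was at 0.507. 3L from 150001 to 160000 was at -3.13 (-3.28 to -2.99), with HP1 at 10.3 in Kc and 1.17 in S2.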

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

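All tests of explanations in this part were chosen after the results were seen.

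In the windows kept by the filter, the median of HP1 was below the autosomal median in S2 and above it in Kc on proximal X and on XHet. On proximal X the median log2 ratio of S2 over Kc was -0.84, with densities of 0.684 (0.564 to 0.737) and 1.22 (1 to 1.33), and on XHet it was -1.03, with 0.921 (0.762 to 1.03) and 1.89 (1.63 to 2.39). The interval of S2 on XHet includes the autosomal level and that of Kc on proximal X reaches it. X as a whole was already lower in S2, with a log2 ratio of -0.73 (-0.84 to -0.61) and densities of 0.605 in S2 and 0.944 in Kc. That ratio lies inside the interval of proximal X (-1.12 to -0.66), so proximal X was not set apart from the rest of X. The interval of XHet (-1.19 to -0.96) lies below it. With all windows kept, both lines fell below the autosomal median, with proximal X at 0.486 in S2 and 0.778 in Kc and XHet at 0.568 and 0.917. The difference between the lines was not tested, since each line has 1 HP1 library.

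YHet, of which 1 of 347 windows entered the values of the Het sequences, had reads in every library, above the 3 reads that a count of 0 allows. The HP1 library from S2 had 200 reads there. The others had 10 (H3K4me2), 28 (H3K9me2), 6 (H3K36me3), 4 (H4K16ac), 17 (H1) and 8 (HP1 in Kc). Of the 200 reads, 183 had a value in column 5 above 3, a kind of read that the other libraries do not hold, and 17 did not.

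HP1 density on X was lower in S2 than in Kc. The reads with column 5 above 3 do not account for this, since the log2 ratio of X stayed at -0.73 without them. Fewer X copies in the male line could account for it, as the HP1 ratio of 0.605 lay within the range of H1, H3K9me2, H3K36me3 and H3K4me2, 0.467 to 0.684. Less HP1 per X copy in S2 cannot be told apart from no such difference. 2 of the 4 reference libraries had a higher X ratio than HP1, and HP1 on X was at 0.885 of H3K4me2 and at 1.30 of H1. X copy number in the Kc cells was not measured.

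HP1 density on chromosome 4 was higher in S2 than in Kc. Reads with column 5 above 3 do not account for it, since the log2 ratio was 0.90 without them. More copies of chromosome 4 in S2 cannot be told apart from more HP1 per copy. Such a gain of 1.86-fold would leave H1 at 0.424 of the autosomal level per copy, which lies above the lowest H1 level of the heterochromatic regions, 0.244 on U. It lies below H1 on the proximal arms (0.689) and on the Het sequences (0.511). Only 22.5% of the windows of U were kept, so U is a weak reference and the comparison does not decide. No library other than HP1 was analysed from Kc, so a loss of chromosome 4 copies there stays open as well.

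The Kc library had 0 reads on 2L from 5001 to 55000 and on 3L from 40001 to 100000, where all 6 S2 libraries had reads. Unplaceable sequence is argued against by the 1960 reads of HP1 in S2 in the stretch of 2L, the lower of the 2 stretches. Absent HP1 with the DNA present is argued against by the other 50-kb stretches in which HP1 of S2 had reads throughout, 19791 overlapping ones, since the lowest of them still held 221 reads in Kc. Stretches without reads in any library, such as 3L from 1 to 40000 and 2L from 21455001 to 21535000, are not among them. Runs of windows with hardly any Kc reads, where HP1 of S2 had reads, were left out as well. A stretch as empty as those of 2L and 3L could therefore not appear among the 19791. No such run was found apart from those of 2L and 3L. A candidate explanation is that these stretches are missing from the DNA of the Kc cells, since 930 reads would be found in the stretch of 2L at the Kc median. Sequence that differs between the Kc line and the reference was not tested.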

How the results depend on the processing

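The alternatives with column 5 of at most 3, the windows with at least 50% of the Kc HP1 median, the local centring of correlations and of H4K16ac classes, and the overlap without the 1 Mb next to the centromere were chosen after seeing the data. No paired analysis was possible because each group holds 1 library. The GC correction, the gene profiles and the gene lists were not run. A value counted as kept when it stayed within its own 95% block interval, or within 1.5-fold for percents of windows. A change of side was counted only where the 95% interval of the reported value excluded no difference. Of 213 pairs of a main value and an alternative, 162 were kept, 46 moved and 5 changed side. Of 497 pairs of other values, 362 were kept, 126 moved and 9 changed side. Values counted as kept or moved may therefore have changed sign, as did the rho of H4K16ac and H1 on X and the log2 ratio of HP1 on 2L. The X to autosome ratios of HP1 in S2, HP1 in Kc and H1 and the log2 ratios of HP1 on X and chromosome 4 were kept under every alternative run for them. Means over windows were not run for the log2 ratios. With means, the densities of HP1 on chromosome 4 were 2.16 in S2 and 1.46 in Kc, closer together than the medians of 2.24 and 1.11. Unless stated, the cause of a change was not tested.

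With all windows, which adds those with reads in fewer than 5 libraries, HP1 in S2 was at 0.973 on the proximal arms, 0.432 on Het, 0.811 on proximal 3L and 0.649 on 3RHet. HP1 in Kc was then at 1.28, 0.333, 0.667 and 0.889 there and at 0.917 on XHet. With H3K36me3 as the reference, the relative X ratio was 1.03 for HP1 and 0.793 for H1. With means, H4K16ac on X was at 2.39, relative to H3K4me2 at 2.92, HP1 relative to H3K4me2 at 0.698, and HP1 in Kc at 1.46 on chromosome 4, 1.99 on the proximal arms and 2.30 on Het.

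In 5-kb windows, HP1 on Het was at 1.09 in S2 and 1.38 in Kc, with a log2 ratio of -0.31. The rho of H4K16ac and HP1 was 0.628 on X and 0.591 on the autosomal arms, and that of HP1 and H3K9me2 0.885. On the autosomal arms the contrast by H4K16ac level was -0.29 for H1 and 0.72 for HP1. The overlap was 4.77 with H3K9me2 and 4.85 with HP1 of Kc, and 2.64% of autosomal windows were 2-fold higher in Kc.

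Thinned to the shallowest library, the rho of H4K16ac with HP1 was 0.488 on X and 0.481 on the autosomal arms, with H1 0.00474 on the arms, that of HP1 and H3K9me2 0.768, and the overlap with H3K9me2 3.84. Lower depth lowers a rank correlation by construction. In windows with at least 50% of the Kc HP1 median, the rho of H1 with H4K16ac was -0.0699 on X and -0.0462 on the autosomal arms, and with H3K4me2 -0.0319 there. The autosomal rho of HP1 was 0.793 with H3K9me2 and 0.496 with H4K16ac. The contrast by H4K16ac level was 0.56 for HP1 on X, and on the autosomal arms 0.71 for HP1 and -0.32 for H1.

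Centred on the surrounding 200 kb, the autosomal rho was 0.728 for HP1 and H3K9me2 and 0.000535 for H4K16ac and H1. HP1 by H4K16ac level was at 0.45 on X and 0.51 on the autosomal arms, and 4.27% and 2.39% of autosomal windows were 2-fold higher in S2 and Kc. A pseudocount of 5 reads gave 0.56 for HP1 by H4K16ac level on X, 4.66% of windows higher in S2 against 7.11% higher in Kc, which turns their order, and -0.047 for proximal 3L.

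At 3 times the median, HP1 by H4K16ac level was 0.87 on the autosomal arms and the overlaps 8.56 with H3K9me2 and 9.94 with HP1 of Kc. With the top 5% of windows, these were 10.5 and 8.37. Scaled to total reads, the log2 ratio of HP1 was -0.29 on Het, 0.0456 on all autosomal arms and 0.0049 on 3L. With column 5 of at most 3, HP1 on Het in S2 was at 1.29 and its log2 ratio at -0.62.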

Other observations

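The tests in this part were chosen after the results were seen.

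On X, the excess of H4K16ac over the autosomal arms was larger in H3K36me3-rich than in H3K36me3-poor windows. Windows with at least 2 times the H3K36me3 median of their chromosome class numbered 6274 on X and 25564 on the autosomal arms. There H4K16ac on X was at 3.55 times the level of the autosomal arms (3.26 to 3.80). In windows below the median it was at 1.14 (1 to 1.29), an interval that reaches 1. These ratios hold the number of X copies, so a value of 1 does not stand for no excess. In the H3K36me3-poor windows the other S2 libraries lay lower, between 0.486 for H1 and 0.714 for H3K9me2 (0.619 to 0.810). H1 was at 0.420 on X (0.373 to 0.480) in the H3K36me3-rich windows and 0.486 (0.447 to 0.528) in the poor ones. HP1 in S2 was at 0.593 and 0.586, HP1 in Kc at 0.893 and 0.929, and H3K4me2 at 1.03 and 0.636.

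Several of the named runs were raised in all S2 libraries at once. In 3R from 19090001 to 19190000, H3K4me2 was at 18.0 times the autosomal median, H4K16ac at 17.0, H3K36me3 at 11.7, HP1 at 5.04, H3K9me2 at 4.58 and H1 at 3.15, with HP1 in Kc at 1.58. In 3R from 25510001 to 25670000, HP1 was at 2.67, H1 at 2.48 and HP1 in Kc at 1.13. In S2, 2 stretches of 10 kb held almost no reads but were rich in Kc, X from 15001 to 25000 (1248 reads in Kc, 2 of HP1 in S2) and 2R from 1155001 to 1165000 (642 and 1). Another, X from 6810001 to 6820000, had 94 and 0 reads.

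The ratio of HP1 in S2 over HP1 in Kc was also taken in 100-kb windows of the autosomal arms. Of 923 windows outside the proximal stretches, 197 had an H3K9me2 density of at least 1.5 times that of H1 in S2. In these, the median log2 ratio of HP1 was 0.57 and 170 windows were above 0. In the other 726 it was -0.09 and 294 were above 0, a difference of 0.66 (0.47 to 0.82). The rank correlation of the HP1 ratio with H3K9me2 over H1 was 0.419 (0.324 to 0.507), which restates this difference and is no separate test of its source. Copies cancel between H3K9me2 and H1, but S2 copy number may itself differ between windows rich and poor in H3K9me2. That value therefore cannot decide whether S2 copy number is the source, although its interval excludes 0. Copy number of S2 stays open, as the HP1 ratio also had a rho of 0.512 (0.424 to 0.590) with H1 alone. Between the 197 and the 726 windows, however, the S2 libraries were not all raised together. Median H1 was at 1.11 and 0.983, H3K4me2 at 0.798 and 1.05, H3K36me3 at 0.879 and 1.03 and H4K16ac at 0.857 and 1.04. These medians have no interval, and the choice of windows by H3K9me2 over H1 itself favours low H1. The rho with H3K4me2 over H1 was -0.163 (-0.231 to -0.0943), so H3K9me2 is not the only mark whose ratio to H1 varied with it. Copy number of Kc, base composition and differences between antibodies or library batches were not tested, and the H3K9me2 level of Kc was not measured.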
